A study of Homo sapiens with 10 samples.

How the data were processed

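Total RNA from 10 samples of A549 cells, 5 without and 5 with crystalline silica at 200 µg/ml for 2 hours, was labelled with biotin and hybridized to Illumina bead arrays, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and each value column was matched to its sample by the name in the description. The submitters' processing notes name BeadStudio, lumi and limma without versions or settings.

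Per the file headers, the authors deposited a BeadStudio table with, for each array, the mean bead intensity, its standard error over beads, a detection p-value against the negative-control beads and a score giving the mean number of beads. The deposited intensity values were not background-subtracted or scaled between arrays. The table has 37846 entries, each with its own symbol cell, and the bead numbers of 6973 (18.4%) are not whole on at least 1 array, so the values are means over the probes of a gene. Of the entries, 25200 have a gene symbol and 12646 do not. Of the former, 20520 were matched to a current symbol through RefSeq gene tables (20467 by Entrez identifier and 53 by accession) and 4680 kept the symbol of the file. The deposited series matrix holds the authors' processed values for 13642 entries, on what looks like a log2 scale by its range. Its column medians were 7.39 on control replicate 1, 7.40 on replicate 2, 7.41 on replicate 3, 7.42 on replicate 4 and 7.39 on replicate 5, and 7.42, 7.41, 7.40, 7.39 and 7.40 on silica replicates 1 to 5. Each of its 10 columns correlated best across genes with the log2 intensity of its own array, with slopes from 0.977 to 1.11 over 1048 bright genes, so the direction is that of the intensities; the transformation, the normalization and the filter are not given in the sources used here.

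From the intensities, values were computed with limma 3.58.1 in R 4.3.3. The function neqc corrected the background by the normal-exponential model, with the mean and SD of the negative controls inferred from the detection p-values, normalized the arrays by quantiles and took log2 after an offset of 16. Normalized values run from 6.458 to 14.92, and the folds of genes near the lower end are compressed, only in part by the offset. Quantile normalization sets the brightest gene, FTL, to one value on every control array. Genes with a detection p under 0.01 on at least 5 arrays were tested, 8306 in all, of which 7991 have a symbol in the file and 4501 were detected on all 10 arrays; 26 share a current symbol with another. A gene not above background on any array of a group has only a bound: its fold is the mean of the brighter group over the higher, per array, of the dim value and the lowest signal above background, written as at least that fold. Groups were compared with lmFit and eBayes, two-sided, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05; a further count required a change of at least 1.5-fold. Standard errors and 95% intervals are those of the moderated fit. No array had more than 1 entry with the same intensity as on another array, and correlations between arrays were from 0.967 to 0.993 across genes, so no sample was taken for a copy of another.

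The 26 gene lists, the rule for naming genes, the tests and the alternatives were fixed before the data were examined. Lists with at least 5 tested members (24 of 26) were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes. Named genes are the 12 largest rises and up to 12 largest falls among changed genes whose groups do not overlap, up to 4 changed members with the largest change from each list or, where none changed, the 2 brightest, and ACTB, GAPDH and B2M; PPIA, also in the rule, did not pass the detection filter. Of the genes taken by this rule, 4 are not reported here. Genes named outside this rule are marked as such or stand as members of a list that did not pass.

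The planned choice of 1 probe per gene, and the alternative of testing probes separately, could not be run because the table is per gene, and the slide could not be used as a block because the files used here do not give it. Alternatives tried were no background correction, an offset of 50, scaling to the array median, the authors' values, no detection filter or a filter on all 10 arrays or at a detection p under 0.05, the replicate number as a block, eBayes with trend and robust, array weights and leaving out each array. Added after seeing the data were leaving out both bright arrays, leaving out silica replicates 1 and 2, the signal scale as a block, entries with a symbol only, and scaling to the median of genes detected on all 10 arrays. In 100 of the possible splits of the arrays into 5 and 5, the real one included, the fit was repeated. On simulated data for the silica comparison with 8306 genes and 200 planted changes, the fit recovered 72% of 50 genes planted at a log2 change of 0.5, 94% at 1 and 100% at 2 and 4; 191 genes were called, 8 of them not planted, and 0 of 23 unchanged lists and 1 of 1 planted list were called. The simulated genes were drawn independently and no simulated array stood apart. The simulation therefore does not show how often lists of correlated genes are called falsely. In the real data the estimated correlation was 0.178 for the immediate-early list. Figures were drawn with matplotlib 3.10.9. No genome was used, and positions are not given.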

Results

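Gene expression was measured in A549 cells, a human lung adenocarcinoma line widely used as a model of the alveolar epithelium, after 2 hours in serum-free medium with crystalline silica at 200 µg/ml or with none. Crystalline silica is a mineral dust whose inhaled particles injure the lung, and the series title names the mechanisms of its pulmonary toxicity as the question. RNA from 5 control and 5 silica samples was hybridized to Illumina bead arrays, 1 sample per array. The labels do not say whether the samples came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The median raw signal was between 67.0 and 77.1 intensity units on 8 arrays, 217 on control replicate 2 and 220 on silica replicate 5. Between 8208 and 9327 genes were above background on 9 arrays, and 5275 were on silica replicate 1. The number of arrays limits the precision of every value below.

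**Figure D1:**
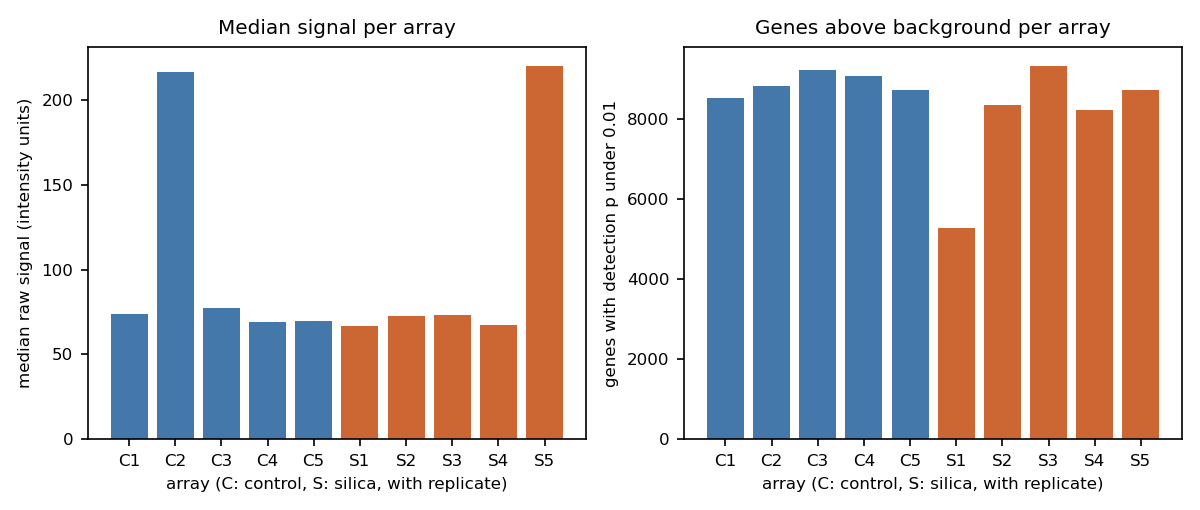
Median raw signal in intensity units (left) and number of genes with a detection p under 0.01 (right) for each array, with control arrays in blue, silica arrays in orange and the replicate number after the letter. Control replicate 2 and silica replicate 5 lie at 217 and 220 units against 67.0 to 77.1 on the other 8 arrays, and silica replicate 1 has 5275 genes above background.

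After 2 hours with silica, transcripts of many immediate-early genes, of some feedback regulators of growth factor signalling and of a few inflammatory mediators were higher. The largest rise was that of CXCL8 (named IL8 in the file), the neutrophil-attracting chemokine interleukin-8, at 4.39 ± 0.22 (log2 ± SE). Its mean log2 signal was 7.90 ± 0.15 (SD, n = 5) in control samples and 12.30 ± 0.52 (SD, n = 5) in silica samples (95% confidence interval of the fold 14.9 to 29.8, limma adjusted p = 2.32e-05). FOSB, a subunit of the AP-1 transcription factor, was 20.2-fold higher (4.34 ± 0.19, log2 ± SE, adjusted p = 1.08e-05). The standard errors do not settle the order of CXCL8 and FOSB. EGR1, an immediate-early zinc finger factor above background on 4 of the 5 control arrays, was 10.1-fold higher (6.64 to 15.3, adjusted p = 0.000331). Its mean log2 value in control samples, 6.63, lay near the lowest normalized value of 6.458, so this fold may be compressed. DUSP5, a phosphatase that inactivates ERK, rose 4.25-fold. PPP1R15A, a phosphatase subunit that reverses eIF2α phosphorylation, rose 3.66-fold, and ZFP36, which destabilises cytokine mRNAs, rose 3.65-fold. The largest of the few falls was that of ID2, an inhibitor of basic helix-loop-helix factors, which was 1.91-fold lower.

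Of 8306 genes tested, 50 changed at a limma adjusted p under 0.05, 43 of them higher and 7 lower with silica. Of these, 35 changed at least 1.5-fold, 32 higher and 3 lower. All 50 had 5 silica values on one side of the 5 control values, as did 170 of the genes tested, which is 2.05% against the 0.794% that chance gives for 5 against 5. The number of calls depended on the scaling between arrays. Scaling each array to its median left 2 genes higher and 0 lower, and scaling to the median of the genes detected on all 10 arrays left 10 higher and 0 lower. It also depended on single arrays. There were 30 genes changed without control replicate 1, 31 without control replicate 2, 29 without control replicate 3, 32 without control replicate 5 and 29 without silica replicate 4. At least 1.5-fold, these were 23, 20, 22, 25 and 23 genes. Of the 43 higher genes, 25 were called in each of the 10 fits that left out 1 array, and 0 of the 7 lower genes were. Among the 25 were CXCL8, FOSB, EGR1, DUSP5, PPP1R15A, ZFP36, JUN, PTGS2, PHLDA1 and the ankyrin repeat gene SOWAHC (ANKRD57 in the file), which rose by 1.56 ± 0.18 (log2 ± SE). RGS2, a regulator of G protein signalling, rose by 1.66 ± 0.28, and its call held without control replicate 4 or silica replicate 2 and was lost in the other 8 of these fits (highest adjusted p 0.112). Among the 8 arrays of the lower signal scale 19 genes changed, all higher, and with the signal scale as a block 46 did. Without silica replicates 1 and 2, which stand apart from the other arrays, 27 changed, 25 of them higher. All 43 higher genes were also higher, and all 7 lower genes lower, in the bright pair alone and among the other 8 arrays. For the bright pair these signs follow from the lack of overlap, and for the other 8 arrays nearly so. They are therefore no separate support. CXCL8 differed by 4.46 (log2) in the bright pair and by 4.51 among the others, FOSB by 4.43 and 4.08, and EGR1 by 3.68 and 2.88.

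**Figure D2:**
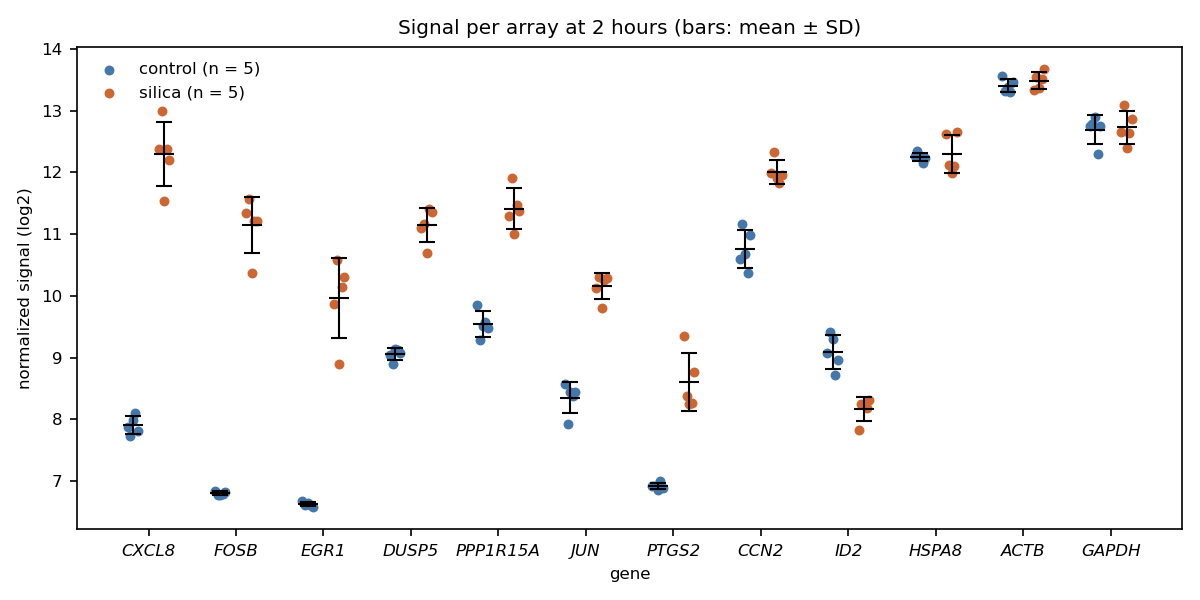
Normalized log2 signal (vertical axis) of 12 genes (horizontal axis) on each of the 5 control arrays (blue points) and 5 silica arrays (orange points), with bars at the mean and 1 SD either side. The silica points of CXCL8, FOSB, EGR1, DUSP5, PPP1R15A, JUN, PTGS2 and CCN2 lie above the control points and those of ID2 below, while those of HSPA8, ACTB and GAPDH overlap, the signs of these last 3 differences changing with the scaling.

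The immediate-early genes, which cells transcribe within minutes of a stimulus without new protein synthesis, rose as a group. Of the 19 list members tested, 10 rose and 0 fell when adjusted over all genes, and 15 rose and 0 fell when adjusted over the list alone (mean log2 difference 1.04, median 0.59, camera adjusted p = 3.16e-33). Besides FOSB and EGR1, ZFP36 rose by 1.87 ± 0.14 (log2 ± SE), JUN, the AP-1 partner of the FOS proteins, by 1.80 ± 0.14, KLF2, a Krüppel-like factor, by 1.53 ± 0.27, and CCN1 (CYR61 in the file), a matricellular protein also held by the SRF and YAP list, by 1.42 ± 0.22. The other 4 that rose, chosen for mention after their values were seen, were IER3 (1.17), MCL1 (0.61), NR4A2 (0.59) and FOSL1 (0.28). In the 10 fits that left out 1 array, the call of IER3 was lost in 9 (highest adjusted p 0.125), that of FOSL1 in 6 (0.0677) and that of MCL1 in 3 (0.0568), while NR4A2 kept its call. FOS itself, above background on 0 of the 5 control arrays and on all 5 silica arrays, was at least 1.63-fold higher and did not pass (adjusted p = 0.196). The mean difference of the list was 0.96 among the 8 arrays of the lower signal scale and 1.16 in the bright pair. With the scale as a block the camera adjusted p was 3.79e-32. Both this value and 3.16e-33 rest on the preset correlation between genes, which is lower than the 0.178 estimated for this list. The camera adjusted p of the list was 0.00217 with the estimated correlation. From 5 to 9 members rose when 1 array was left out, with 5 without control replicate 1, control replicate 3 or silica replicate 4, and 6 without control replicate 2, 4 or 5. Without both bright arrays 5 rose, and without silica replicates 1 and 2 together 6 did. With scaling to the array median 1 member rose, FOSB (mean of the list 0.80), and with scaling to the median of genes detected on all 10 arrays 5 did. The call of KLF2 was lost in each fit that left out 1 array except that without silica replicate 2 (highest adjusted p 0.131). That of CCN1 was lost in each except those without silica replicate 1 or 5 (0.0805).

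Targets and feedback inhibitors of the EGF receptor and MAP kinase pathway were also higher. Of 17 members tested, 3 rose and 0 fell over all genes, and 10 rose and 0 fell when adjusted over the list alone (mean 0.44, median 0.22, adjusted p = 4.48e-16). The 3 were DUSP5 at 2.09 ± 0.12 (log2 ± SE), PHLDA1, a pleckstrin homology-like protein induced by growth factors, at 1.63 ± 0.13, and ETS1, a transcription factor downstream of ERK, at 0.72 ± 0.09. The mean difference was 0.42 among the 8 arrays of the lower signal scale and 0.50 in the bright pair, and the adjusted p was 1.51e-15 with the scale as a block. With an estimated correlation between genes, 0.0310, the camera adjusted p of the list was 0.00177. DUSP5, PHLDA1 and ETS1 kept their calls in each fit that left out 1 array, and ETS1 lost its call without both bright arrays (adjusted p = 0.0645). With scaling to the array median 0 members rose (mean of the list 0.28), and with the other median scaling 2 did.

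Among inflammatory genes regulated by NF-κB, a few members moved far and most did not. Of 19 tested, 5 rose and 0 fell over all genes and 7 rose and 0 fell when adjusted over the list alone (mean 0.56, median 0.04, adjusted p = 3.00e-12). Besides CXCL8, these were PTGS2, the inducible cyclooxygenase, at 1.68 ± 0.20 (log2 ± SE), the cytokine IL11 at 1.28 ± 0.17, the apoptosis inhibitor BIRC3 at 0.99 ± 0.16, and IL6 at 0.29 ± 0.04. BIRC3 was above background on 4 of the 5 silica arrays. Its highest silica value, 8.50, was on replicate 1, where it was not above background. IL6 was named after its value was seen. Its mean log2 values, 6.60 in control and 6.89 in silica samples, lay near the lowest normalized value of 6.458. IL6 was above background on 4 of the 5 control arrays. The chemokine CCL2 (0.86, adjusted p = 0.167), NFKBIA (0.52, adjusted p = 0.265) and TNFAIP3 (0.03, adjusted p = 0.872) did not pass. The mean difference was 0.50 among the 8 arrays of the lower signal scale and 0.63 in the bright pair, with an adjusted p of 1.38e-11 with the scale as a block. The camera adjusted p of the list was 0.00985 with an estimated correlation between genes, 0.0906. Without both bright arrays 1 member rose, CXCL8, and PTGS2 no longer passed (adjusted p = 0.146). Of the 19 members, 3 rose without control replicate 2, 1 with scaling to the array median (CXCL8, mean of the list 0.41) and 2 with the other median scaling. The call of IL11 was lost without control replicate 2 (adjusted p = 0.0503) and that of BIRC3 in each fit that left out 1 array except those without silica replicate 3 or 5 (highest adjusted p 0.107).

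Another 4 lists were higher, each through fewer members. In the list of ATF4 and endoplasmic reticulum stress genes, 1 of 20 rose over all genes (PPP1R15A) and 5 when adjusted over the list alone, with 0 lower (mean 0.27, adjusted p = 3.84e-06). Its call was lost with an estimated correlation (adjusted p = 0.0565). DDIT3, the stress factor CHOP, differed by 0.17 (adjusted p = 0.674). In the list of SRF and YAP targets, 2 of 19 rose over all genes, CCN1 and the matricellular CCN2 (CTGF in the file; 1.25 ± 0.15, SE), while 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000117). Its mean was 0.25, and its median of 0.06 turned to -0.01 with scaling to the array median. Without silica replicates 1 and 2 together 0 of these 19 members rose. In the apoptosis list, 1 of 19 rose over all genes, the TRAIL receptor TNFRSF10A (0.49 ± 0.05, SE), and 3 when adjusted over the list alone (camera adjusted p = 0.00186). Its mean was 0.09, which became -0.04 with scaling to the array median, where the call was lost (adjusted p = 0.0656). In the list of growth-arrest and repressor transcription factors, BHLHE40 (BHLHB2 in the file), a circadian and hypoxia-responsive repressor, and the coactivator CITED4 rose by 1.23 ± 0.20 and 0.99 ± 0.08 (log2 ± SE) while ID2 fell. Over all genes these were the 2 of 12 that rose and the 1 that fell, and 5 rose and 2 fell when adjusted over the list alone (mean 0.16, adjusted p = 0.00272). The call of this list was lost with an estimated correlation (adjusted p = 0.214). The other 5 of the 7 calls held with an estimated correlation, with adjusted p from 0.00177 to 0.0250. In the bright pair and among the other 8 arrays, the mean differences were 0.34 and 0.24 for the stress list, 0.23 and 0.27 for the SRF and YAP list, 0.07 and 0.09 for the apoptosis list and 0.23 and 0.12 for the repressor list. With the scale as a block, their adjusted p were 9.56e-06, 0.000121, 0.00276 and 0.00482. With scaling to the array median 0 members of these 4 lists rose, and with the other median scaling 1 did in each of the first 2 and 0 in the last 2. In the stress list 3 members rose without silica replicate 2, and in the apoptosis list 2 without silica replicate 1. In the SRF and YAP list 1 rose without control replicate 1, 2 or 5 or silica replicate 2, 3 or 4, and in the repressor list 1 rose in each fit that left out 1 array except that without silica replicate 3. The call of BHLHE40 was lost in each except that one (highest adjusted p 0.0880), while PPP1R15A, CCN2, TNFRSF10A and CITED4 kept theirs.

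**Figure D3:**
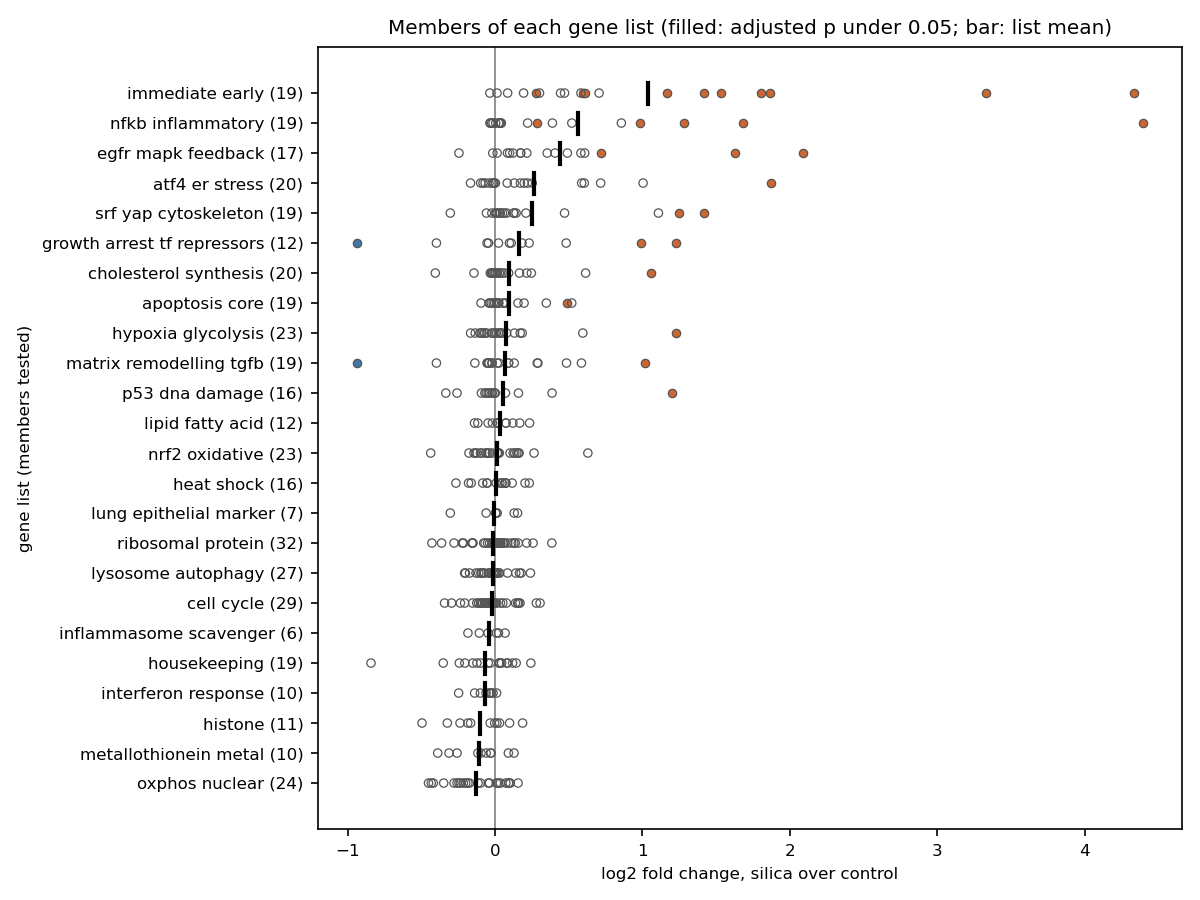
Log2 fold change of silica over control (horizontal axis) for each tested member of 24 gene lists (vertical axis, with the number tested), where filled points have an adjusted p under 0.05 (orange higher, blue lower), open points do not, and the vertical bar is the mean of the list. The immediate-early list has 10 filled points and a mean of 1.04, and the mean of the apoptosis list, 0.09, changes sign with scaling to the array median.

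Single members rose in lists that did not shift as a whole. GADD45A, a growth-arrest gene induced by DNA damage, was 2.30-fold higher and was the 1 of 16 members of the p53 list to pass (camera adjusted p = 0.942; mean above 0, median below). PLAU, the urokinase plasminogen activator, was 2.02-fold higher while ID2 fell in the same list of 19 matrix and TGF-β genes (adjusted p = 0.175), and BHLHE40 was the 1 of 23 hypoxia and glycolysis genes to pass (adjusted p = 0.364). Adjusted over the list alone, 1 member rose in the p53 list, 3 in the matrix list, where 2 fell, and 2 in the hypoxia list. GADD45A kept its call in each fit that left out 1 array, and PLAU lost its call in each except that without silica replicate 4 (highest adjusted p 0.0909). The cholesterol list of 20 members did not pass (adjusted p = 0.0548), and passed without control replicate 2 (adjusted p = 0.0266), control replicate 3 (0.0193) or silica replicate 4 (0.0271), and the matrix list without silica replicate 4 (0.0489).

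Genes of oxidative, heat and metal stress did not pass. Of 23 NRF2 targets and oxidative stress genes, 0 passed over all genes and 2 rose when adjusted over the list alone (limma camera adjusted p = 0.776, with a median below 0 and a mean above). The aldo-keto reductase AKR1B10 differed by 0.26 (log2, adjusted p = 0.135), the ferritin light chain FTL by -0.05 and haem oxygenase HMOX1 by -0.44 (adjusted p = 0.442). The heat shock list had 0 of 16 members past the threshold (adjusted p = 0.658), with HSPA8 at 0.05 and DNAJA1 at 0.12, and the metallothionein list 0 of 10 (adjusted p = 0.776), with MT2A at -0.31 and MT1A at -0.12. In the lipid synthesis list 0 of 12 members passed (adjusted p = 0.476), with FASN at 0.23 and ACLY at 0.12. Of 29 cell cycle genes 0 passed (adjusted p = 0.776), with MCM6 at 0.08 and TOP2A at -0.10. Of 27 lysosome and autophagy genes 0 passed (adjusted p = 0.947, the test and the mean differing in sign), with NPC2 at -0.17. The interferon list had 0 of 10 past the threshold (adjusted p = 0.374), with TAP1 at -0.10. The inflammasome and scavenger receptor list had 0 of 6 (adjusted p = 0.776), with IL18 at 0.07 and SCARB2 at 0.02. Of 11 histone genes 0 passed (adjusted p = 0.476), with H2AZ1 at 0.10 and H2BC12 at -0.17, and of 32 ribosomal protein genes 0 passed (adjusted p = 0.830, median and mean differing in sign), with RPS3 at -0.01 and RPL18 at 0.22. Nuclear genes of oxidative phosphorylation had a median of -0.14 with 0 of 24 past the threshold (adjusted p = 0.0960; ATP5F1B -0.20, COX4I1 -0.11), and the list passed without control replicate 4 (adjusted p = 0.00569). Over all these lists, adjusted over the list alone, 1 further gene passed, in the lysosome list. At an unadjusted p under 0.05, 625 of all 8306 genes passed in limma.

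Of the 7 genes that were lower, 3 fell at least 1.5-fold, the largest fall being 1.91-fold. ID2 fell by 0.93 ± 0.14 (log2 ± SE, adjusted p = 0.0209), MIR503HG (MGC16121 in the file), a long non-coding RNA, fell by 0.87 ± 0.14, and MPC2 (BRP44 in the file), a subunit of the mitochondrial pyruvate carrier, fell by 0.68 ± 0.12. CCDC77 fell by 0.39, DECR2, a peroxisomal reductase, fell by 0.38, and IKBKG, the regulatory subunit of the IκB kinase, fell by 0.37. AXIN2, a negative regulator of Wnt signalling, fell by 0.21 and was above background on 1 of the 5 silica arrays. Its mean log2 values, 6.78 in control and 6.58 in silica samples, lay near the lowest normalized value of 6.458, which limits its fold. The call of ID2 was lost in 3 of the 10 fits that left out 1 array (without control replicate 1, control replicate 3 or silica replicate 4, highest adjusted p 0.0677). That of MIR503HG was lost in 5, without control replicate 1, 2 or 3 or silica replicate 1 or 4 (0.0805). Those of the others held only without control replicate 1 or silica replicate 1 for MPC2, control replicate 1 or 5 or silica replicate 1 for CCDC77, control replicate 1 or 3 or silica replicate 5 for DECR2, control replicate 3 for IKBKG, and control replicate 2 or silica replicate 1 or 2 for AXIN2. The highest adjusted p among these was 0.133, for MPC2. Each of the 7 kept its sign in these fits, which nearly follows from the lack of overlap between the groups. Without silica replicate 1, the array with the fewest genes above background and the lowest ID2 value, ID2 fell by 0.86.

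Markers of other cell types and control genes did not pass over all genes. Of 21 leukocyte and macrophage markers 1 was tested, CD68, which differed by 0.0027 (log2, adjusted p = 0.992). Of 20 fibroblast and endothelial markers 4 were tested, with ACTA2 at -0.17 and COL1A1 at -0.08. In these lists 0 genes passed. The lung epithelial list had 0 of 7 members past the threshold over all genes (adjusted p = 0.942, median and mean differing in sign). The keratins KRT7 and KRT8 differed by 0.0043 and -0.30, and KRT8 was lower when adjusted over the list alone. Of 19 housekeeping genes 0 passed over all genes (adjusted p = 0.942, median and mean differing in sign) and 1 was lower when adjusted over the list alone. With scaling to the median of genes detected on all 10 arrays the housekeeping list passed as lower (adjusted p = 0.00102), as did the cell cycle (0.00142), metallothionein (0.00787), heat shock (0.0477), ribosomal protein (0.000287) and oxidative phosphorylation (5.03e-11) lists. ACTB differed by 0.08 (adjusted p = 0.846), GAPDH by 0.03 (0.970), B2M by -0.15 (0.915) and EEF1A1 by 0.03 (0.902). The signs for ACTB, GAPDH and EEF1A1 changed with the alternative.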

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

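The comparison of silica replicate 1 with the control arrays and the count of splits for each list were tests chosen after the result was seen. In groups of 5, a value is listed here when its gap to the nearest other value, divided by the range of the group, exceeds Dixon's 95% limit. This held for 15 of 124 groups of values, of which 9 were gene values, and chance alone gives about 1 in 20.

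The higher immediate-early, EGF receptor and NF-κB lists in silica samples were set against chance and array quality. Among 100 splits of the 10 arrays into 5 and 5, the real one alone gave as many changed genes. It gave 50 against at most 2 in the others, and 35 against at most 1 for genes changed at least 1.5-fold. Chance is thus unlikely for both counts, but 100 splits cannot show a share under 1 in 100. For the number of shifted lists chance stays open, since 7 splits, the real one included, gave at least the real 7. The highest other gave 9. For the immediate-early, EGF receptor and NF-κB lists, no other drawn split gave as low a camera p, nor for the stress and apoptosis lists. For the SRF and YAP list and for the repressor list, 3 of the 100 splits did, the real one included. Without silica replicates 1 and 2 the mean change of the immediate-early, EGF receptor and NF-κB lists was 0.968 times that with all arrays. Its 95% bootstrap interval over genes was 0.933 to 1.01. Without both bright arrays the mean change was 0.918 times that with all arrays (0.86 to 0.964). The mean change of these lists thus did not rest on either pair. The intervals resample genes and do not measure the spread between arrays. The bright pair holds 1 array of each group, so its signal scale is balanced over the groups. A response to silica stays a hypothesis. Another difference between the groups, such as in the cultures, which the labels do not describe, could not be told apart from it.

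Silica replicate 1 had 5275 genes above background against 8208 to 9327 on the other silica arrays (gap over range 0.724), and its ratio of the 95th percentile to the median signal was 2.15 against 6.31 to 7.78 (0.739). A control sample under a silica label is argued against by a comparison with the control arrays: 81.8% of the 44 genes changed without this array lay nearer the silica mean on it (exact 95% interval 67.3 to 91.8), against at most 16.2% on any control array. This stays below the 90% set in advance, so the rule set in advance leaves it undecided. The interval treats the genes as independent, which genes that move together are not. Lower signal across genes may account for the fewer genes above background, since the median ratio of the array's signal above background to that of the other silica arrays of its scale was 0.186 in the brightest of 5 equal groups of genes (quartiles 0.161 and 0.221). The ratio was 0.192, 0.214 and 0.258 in the next groups and 0.346 in the dimmest (quartiles 0.196 and 0.506). Some background may remain in the values of dim genes and raise their ratio. These ratios therefore do not show whether the loss was equal over genes. No biological explanation was tested for this array.

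Median signal stood apart on control replicate 2 (217, gap over range 0.946) and silica replicate 5 (220, 0.960), as did mean signal (659, 0.965, and 598, 0.793). On silica replicate 1, ID2 was at a log2 value of 7.82 against 8.18 to 8.32 (0.734), FASN at 12.66 against 11.47 to 11.72 (0.791) and TAP1 at 7.94 against 8.57 to 8.74 (0.796). MT1A was at 11.21 on silica replicate 2 against 12.02 to 12.34 (0.713). BHLHE40 was at 9.33 on control replicate 2 against 9.91 to 9.97 (0.908). On control replicate 1, KRT7 was at 13.05 against 12.56 to 12.63 (0.844) and KRT8 at 11.19 against 10.91 to 10.98 (0.734). ACTA2 was at 9.54 on control replicate 5 against 9.66 to 9.69 (0.771), and GAPDH at 12.29 on control replicate 4 against 12.75 to 12.90 (0.753).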

How the results depend on the processing

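Leaving out both bright arrays or silica replicates 1 and 2, the scale as a block, entries with a symbol only and the second median scaling were chosen after seeing the data. All 30 named genes past the threshold kept their sign wherever they were tested, in 26 alternatives with a gene fit for 27 of them and in 25 for EGR1, BIRC3 and AXIN2, which the filter on all 10 arrays leaves out. Their groups do not overlap and the alternatives use the same arrays, so the kept signs nearly follow and are no separate support. Of the 30, only 2, CXCL8 and FOSB, kept their call in all 26 alternatives. Of the 32 named genes not past the threshold, 0 passed in any alternative. Genes changed, and those changed at least 1.5-fold, went from 50 and 35 to 2 and 2 with scaling to the array median, 10 and 10 with scaling to the median of genes detected on all 10 arrays, 29 and 22 with no filter over the 25200 entries with a symbol, 19 and 16 without both bright arrays and 27 and 19 without silica replicates 1 and 2, the last 2 with fewer samples. The fit without a filter also drops entries without a symbol, which with the filter kept left 50 and 35. Leaving out each array gave 29 to 44 and 20 to 30, and 7 to 9 shifted lists. The authors' values gave 43 and 30, of which 37 and 27 were among the 50 and 35.

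Scaling to the median of detected genes shifted 12 lists, 6 up and 6 down, against 7; heat shock (0.0477, range 0.0477 to 0.958) and ribosomal proteins (0.000287, range 0.000287 to 0.977) turned down there. Housekeeping (0.00102, range 0.00102 to 0.986), cell cycle (0.00142, range 0.00142 to 0.970) and metallothionein (0.00787, range 0.00787 to 0.940) passed as lower, as did oxidative phosphorylation (5.03e-11, range 5.03e-11 to 0.623). The apoptosis list lost its call there (adjusted p = 0.154), as with scaling to the array median (0.0656; range over alternatives 0.000625 to 0.154). The stress list lost its call with an estimated correlation (0.0565; range 1.69e-07 to 0.0565), and the repressor list there (0.214) and with fry (0.0597; range 0.000541 to 0.214). The cause was not tested for any of these. The immediate-early, EGF receptor, NF-κB and SRF and YAP lists passed in all 28 alternatives. Cholesterol synthesis passed in 9 and oxidative phosphorylation in 6.

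The replicate numbers showed no clear pairing of the samples. Deviations of arrays with the same title number correlated at -0.0993, -0.394, -0.0499, 0.236 and 0.0713 across genes. Of 5 silica arrays, 1 was closest to the control of its own number. So few correlations cannot exclude a pairing, and title number 3 joins description numbers 3 and 4. With the title numbers as a replicate block 12 genes changed, 11 of them at least 1.5-fold, and with the description numbers, shared by 8 arrays, 6 and 6. Testing probes separately and the slide as a block were not run. Signal over background limits the folds of dim genes and the values of silica replicate 1, whose array weight was 0.196.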

Other observations

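The 2 tests on the direction of change were chosen after the result was seen. Of the 50 changed genes, 23 were in none of the fixed lists. The largest rise among them outside the named genes was that of STC1, a secreted glycoprotein, at 1.47 (log2), which kept its call in each fit that left out 1 array. GDF15, a stress-induced cytokine of the TGF-β family, rose by 1.10, FOXD1, a forkhead factor, by 0.99, IRAK2, a kinase of interleukin-1 receptor signalling, by 0.88, and JAG1, a Notch ligand, by 0.55; IRAK2 kept its call in each of those fits, while GDF15 lost it in 7, FOXD1 in 6 and JAG1 in 9 of the 10. These genes were chosen after their values were seen.

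More genes were higher than lower, 86% of the 50. Whether the scaling between arrays is the source stays open. The lowest share of higher genes under the authors' values, no background correction and scaling to the array median was 86%, with the authors' values. Scaling to the array median called 2 genes, too few for a share to decide, and scaling to the median of genes detected on all 10 arrays shifted 6 lists up and 6 down. A floor under dim genes that hides falls stays open too: of the 17 changed genes with a mean log2 value over 9 in control samples, 14 were higher (82.4%, exact 95% interval 56.6 to 96.2), too few to decide. Other explanations, including a time of 2 hours that may be too short for stable transcripts to fall, were not tested.

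A hypothesis for the fall of ID2 was lower BMP signalling, which would lower its other targets. The 5 other targets tested had a median of -0.0543 and a camera p of 0.309, with ID1 at -0.40 (adjusted p = 0.114), which leaves it open. A hypothesis for the fall of AXIN2 was lower Wnt signalling. The 7 other targets had a median of 0.0296 and a camera p of 0.0343 in the direction of higher (0.113 with an estimated correlation), the opposite of what it needs. A median that is not negative had been set in advance as counting against this hypothesis. It is left open here, because 4 members were higher and 3 lower and the camera p did not hold with an estimated correlation.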
